A study of Mus musculus with 3 samples.

How the data were processed

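Single-cell RNA was measured in sorted liver macrophages from 3 male mice aged 8 weeks, 1 on chow, 1 after 3 days and 1 after 10 days of a Lieber-DeCarli liquid diet with 5% ethanol. Per the labels, non-parenchymal cells were freed by collagenase perfusion, sorting then kept viable cells with high F4/80 and intermediate CD11b, and libraries were made with the 10x Genomics Chromium 3' v2 kit. The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and barcode, before any choice of cells. Cell Ranger 2.2.0 and the mouse builds GRCm38 and mm10 are named in the submitters' processing notes. The annotation release, the cell calling and the aligner settings were not given in the sources used here. Gene coordinates were taken from GENCODE vM21 on GRCm38, in which 28416 of the 28692 gene IDs in the files were found, 27266 of them with the same symbol.

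The libraries held 21650747 UMIs (chow), 21471782 (3 days) and 16538895 (10 days). Their numbers of barcodes with a UMI were 381550, 390039 and 334603. A barcode was called a cell when its UMI count reached 1/10 of the count at the 99th percentile of the 3000 largest barcodes of its library. The resulting minimum was 1186 UMIs in chow, 926 at 3 days and 816 at 10 days, and the called cells held 65.4%, 68.2% and 67.1% of the UMIs. Cells with fewer than 300 genes (13, 19 and 46 cells) or with over 10% mitochondrial UMIs (205, 296 and 521 cells) were removed. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0.183%, 0.0244% and 0.0325% of cells, so the 4% of cells left after these filters with the highest scores were removed instead (109, 164 and 123 cells). This replacement was not part of the fixed design.

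The remaining cells of the 3 libraries were clustered together without batch correction. Each library was 1 group, so such a correction cannot tell a difference between diets from one between libraries. It would act on the clusters and not on the raw counts that were summed, and clustering with it was not run. Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6 were used (igraph 0.11.9, scikit-learn 1.9.0). A cluster was named from fixed marker lists when at least 3 markers of 1 cell type were among its 25 leading genes. Leading genes had at least 50 CPM (UMI counts scaled to a common library total) and a fold of at least 2 against all other cells, with 20 CPM added to both sides. Leading genes seen in under 25% of the cluster's cells were left out unless their share of cells was at least 2 times that elsewhere. A cluster was Kupffer-like when its median level of Kupffer identity genes was at least 0.5 of that in all cells and no other type reached 3 markers. Clusters that met both criteria were left unnamed as mixed, except a cluster led by proliferation genes, which was kept in the Kupffer-like sums. The thresholds for naming clusters were set after a first clustering had been seen.

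Counts of the Kupffer-like cells were summed per library and divided by their total to give CPM. Log2 ratios had 1 CPM added to both sides, and printed ratios had nothing added. Each ratio has an exact conditional binomial 95% interval and each share an exact Clopper-Pearson 95% interval. A share of 0 was given the upper limit that 3 counts would make. There were no replicates, so no test between groups was run, and these intervals cover counting error only. They say nothing about differences between mice, sorts or libraries.

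The named genes were those with the 10 highest and 10 lowest log2 ratios in each comparison with chow, and the 5 highest and 5 lowest for 10 days against 3 days. They needed at least 50 CPM in 1 library of the compared pair and a 95% interval that excluded 1. Mitochondrially encoded genes, ribosomal protein genes, genes with only a provisional Gm or Rik symbol, and members of the hepatocyte and erythroid lists were left out of this ranking. Groups of genes were described by lists written from general knowledge. A list member was measured when its mean over the 3 libraries was at least 10 CPM in Kupffer-like cells, a level that 7514 genes reached. For list medians in T and NK-like and in endothelial-like cells the limit was 50 CPM, so the members differ from those in Kupffer-like cells. The median log2 ratio of a list was placed among the medians of 10000 random lists of equal size, drawn from the same 20 bins of expression. This percentile is a description of these libraries, not a test, since genes of a list move together. Numbers of members with a ratio above 1.5 or below 1/1.5 are given beside it. Lists with fewer than 5 measured members are not described, except the erythroid list, which the rules for ranking and for free RNA use, and 2 members per list are given as examples. Both limits were set after the effect of other settings had been seen. The wider set of 371 gene results, which also holds the 126 kept here, gave 145 reversals among 8533 values. Of these reversals, 110 were under the planned subtraction of free RNA.

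The share of cells with a UMI of a gene was computed after thinning every cell at random to 1500 UMIs, because the libraries differed in depth. Cells with fewer UMIs were left out of it. Free RNA was taken from barcodes with at least 10 and fewer than 100 UMIs. Ratios were also recomputed within each Kupffer-like cluster. The clusters mostly follow the libraries, so these ratios cannot separate differences in level between libraries from differences in the mix of clusters.

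The alternatives covered cell calling (top 5000 barcodes, at least 1000 UMIs, or the 3000 largest barcodes), mitochondrial limits of 5% and 20%, at least 500 genes, doublets kept, and Leiden resolutions of 0.3 and 1.0. They also covered variable genes chosen within libraries, TMM scaling with edgeR 4.0.16, median-of-ratios scaling, equal weight per cell, thinned cells, and a pseudocount of 5 CPM. The last group was all kept cells, Kupffer-like cells without the proliferating cluster, no filter or a 50 CPM filter on list members, and subtraction of free RNA. Subtraction followed the planned rule, which sets the level of hepatocyte and erythroid genes to 0. Added later were subtraction with a share taken from Kupffer transcripts in T and NK-like cells, leaving out clusters 1, 2 or 8, and equal weight per cluster. Equal weight gives small clusters, such as cluster 8 with 44 cells in chow, the weight of cluster 3 with 1347. A median that moves under it may therefore follow a few small clusters. The filters, cluster settings, comparisons, gene lists, rule for named genes and the alternatives other than those added later were chosen before the data were examined.

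The steps that follow the summing of Kupffer-like counts were tested on simulated sums with known folds of 1.5, 2 and 3. These sums held counting error alone, so coverage near 95% follows from their construction. Cell calling, filters, doublet removal, clustering and the naming of clusters were not tested in this way. The direction of 100% of the genes with a simulated fold was recovered. The intervals covered the true ratio for 95.2%, 95.4% and 95.5% of genes in the 3 comparisons. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.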

Results

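Kupffer cells are the resident macrophages of the liver sinusoids, where they clear particles, old red cells and gut-derived bacterial products from portal blood. The study sequenced RNA of single cells sorted as F4/80-high and CD11b-intermediate from 3 male mice aged 8 weeks. The groups were chow, 3 days and 10 days of a Lieber-DeCarli liquid diet with 5% ethanol, each with 1 mouse and 1 library. There were no replicates, and a difference between mice, libraries or preparations cannot be told apart from one due to the diet. The control ate chow rather than a liquid diet without ethanol, so ethanol and the form of the diet varied together.

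The libraries held 21650747 UMIs (chow), 21471782 (3 days) and 16538895 (10 days). The labels state an average yield of 3000 to 5000 cells per sample. The files held 381550, 390039 and 334603 barcodes with a UMI, of which 2944, 4410 and 3640 were called cells and 2617, 3931 and 2950 were kept. Kept cells had medians of 4520 UMIs in chow, 2991 at 3 days and 2892 at 10 days, so the chow cells were the deepest. Their medians of genes were 1863, 1441 and 1409, and their medians of mitochondrial UMIs were 5.09%, 5.12% and 6.30%. After the filters for genes and mitochondrial UMIs, the 4% of remaining cells with the highest doublet scores had been removed from each library.

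Kupffer-like cells made up 87.0% of the kept cells in chow (2277 cells, 95% interval 85.7% to 88.3%). The share was 89.4% at 3 days (3516 cells, 88.4% to 90.4%) and 87.6% at 10 days (2585 cells, 86.4% to 88.8%). These shares describe what passed the F4/80-high, CD11b-intermediate sort, not the liver. With a mitochondrial limit of 5% in place of 10% the shares were 80.3%, 85.5% and 61.0%. T and NK-like cells were 4.39% (3.64% to 5.25%), 2.29% (1.84% to 2.81%) and 5.19% (4.41% to 6.05%) of kept cells. Endothelial-like cells were 1.45%, 2.70% and 2.41%, and conventional dendritic-like cells 2.41%, 1.14% and 0.983%. Hepatocyte-like cells were 0.267%, 0.204% and 0.780%, and B and plasma-like cells 0.764%, 0.204% and 0.441%. Clusters 7 and 13 carried Kupffer markers together with markers of other immune cells. They were left unnamed and held 3.67%, 3.87% and 2.54% of kept cells.

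The Kupffer-like cells formed 7 clusters. Clusters 1 to 5 each came mostly from 1 library and may be that library rather than a cell state. Cluster 3 held 59.2% of the Kupffer-like cells of chow. Clusters 4 and 1 held 37.0% and 33.3% of those at 3 days, and clusters 2 and 5 held 38.5% and 34.7% of those at 10 days. Cluster 1 was led by globin genes, but 10 cells held 76.0% of all Hbb-bs UMIs. Of its cells 8.45% had an Hbb-bs UMI, against 7.55% of all kept cells. With genes left out that few cells held at a share like that elsewhere, Vcam1, Hmox1, BC005537 and Engase led it. Cluster 8 was led by the immune genes Cxcl10, Cxcl9 and Cxcl2, which handling can also induce. Proliferating cells were 1.83%, 1.48% and 1.90% of kept cells and stayed in the Kupffer-like sums. All values below, unless another class is named, are sums over these Kupffer-like cells, which held 10970793, 11481428 and 8347122 UMIs. Their median depths were 4573, 2977 and 2964 UMIs per cell.

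Kupffer identity genes encode the lectins, scavenger receptors and transcription factors that separate resident liver macrophages from other macrophages. All 28 members of this list were measured, and their medians stayed inside the range of random lists in each comparison. Clusters were called Kupffer-like only when their median level of these same genes was at least 0.5 of that in all cells. A cluster with a larger loss would have been left out, so values of identity genes here are partly set by that choice. The median log2 ratio was −0.03 at 3 days over chow (mean 0.02), 0.02 at 10 days over chow and 0.03 at 10 days over 3 days. Clec4f, a lectin receptor used as a Kupffer marker, had a UMI in 99.5%, 99.5% and 99% of Kupffer-like cells thinned to 1500 UMIs (unthinned 99.9%, 99.6% and 99.5%). In thinned T and NK-like cells, which lack the gene, its share was 47.4%, 47.8% and 43.9%, which is free RNA. Cd5l, a secreted apoptosis inhibitor, was seen in 99.7%, 99.8% and 99.6% (unthinned 100%, 99.8% and 99.8%), beside 48.2%, 48.9% and 52.0% in T and NK-like cells. Timd4, a receptor for dying cells carried by long-lived Kupffer cells, was seen in 52.8%, 46.7% and 46.9% (unthinned 83.2%, 69.1% and 68.7%). Its background was 7.02%, 2.22% and 6.08%. The median depths of T and NK-like cells were 3538, 2615 and 2448 UMIs. Thinning left out 76, 348 and 276 Kupffer-like cells and 1, 0 and 5 T and NK-like cells.

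Among scavenger receptors, Cd163, which takes up haemoglobin bound to haptoglobin, was seen in 51.3% (49.2% to 53.4%), 74.1% (72.5% to 75.6%) and 52.1% (50.0% to 54.2%) of thinned cells. The unthinned shares were 76.6%, 85.6% and 70.0%, and the background shares 4.39%, 13.3% and 6.08%. The fatty acid receptor Cd36 was seen in 13.9% (12.4% to 15.4%), 21.7% (20.3% to 23.2%) and 32.8% (30.9% to 34.7%), unthinned 29.2%, 35.6% and 51.7%. Its background was 0.877%, 0% (which allows up to 3.33%) and 3.38%. The mannose receptor Mrc1 was seen in 74.0%, 85.5% and 85.6% (unthinned 97.0%, 97.6% and 97.3%), with 10.5%, 10.0% and 13.5% as background. The bacterial scavenger receptor Marco was seen in 25.2%, 23.9% and 34.7% (unthinned 42.6%, 34.7% and 47.9%), with 6.14%, 3.33% and 7.43%. Hmox1, the haem-degrading enzyme, was seen in 71.3%, 82.9% and 86.3% (unthinned 93.1%, 94.1% and 95.7%), beside 16.7%, 21.1% and 26.4%.

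Cd74, the invariant chain of class II antigen presentation, was seen in 98.8%, 97.6% and 97.4% of thinned cells (unthinned 99.8%, 98.5% and 98.3%), beside 50.9%, 23.3% and 35.1% in T and NK-like cells. The cytokine gene Il1b was seen in 32.1%, 34.7% and 29.9% (unthinned 57.8%, 52.4% and 44.5%), beside 3.51%, 1.11% and 2.03%. Trem2, a lipid-sensing receptor of damage-associated macrophages, was seen in 5.32%, 7.07% and 4.42% (unthinned 14.3%, 12.3% and 8.01%), beside 0% (up to 2.63%), 1.11% and 0.676%. The neutrophil attractant Cxcl2 was seen in 0.545%, 1.33% and 0.953% (unthinned 1.36%, 2.30% and 1.74%). No T or NK-like cell had a Cxcl2 UMI, which allows shares of up to 2.63%, 3.33% and 2.03%.

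Several genes were seen in few cells. Tnf, a proinflammatory cytokine gene, was seen in 1.04%, 1.14% and 0.780% of thinned cells (unthinned 2.55%, 2.13% and 1.62%), beside 0.877%, 1.11% and 0.676%. The division marker Mki67 was seen in 1.36%, 1.55% and 1.08% (unthinned 3.82%, 3.01% and 2.40%), beside 0.877%, 0% (up to 3.33%) and 1.35%. The monocyte genes Ccr2 and Ly6c2 were seen in 0.772%, 1.2% and 0.953%, and in 0.273%, 0.221% and 0.303%, of thinned cells. Their unthinned shares were 1.54%, 2.25% and 1.55%, and 1.32%, 0.597% and 0.658%. T and NK-like cells express both genes, at 25.4%, 28.9% and 23% for Ccr2 and 20.2%, 26.7% and 15.5% for Ly6c2, so they give no background level for these. Esam, a junction protein named as a marker of a Kupffer subset, was seen in 0.136%, 0.189% and 0.217% (unthinned 0.571%, 0.484% and 0.542%) and in 0% of T and NK-like cells (up to 2.63%, 3.33% and 2.03%). The matrix protein gene Spp1 was seen in 0% of chow cells, which allows a share of up to 0.136% in thinned cells, and in 0.126% and 0.217% of the others (unthinned 0%, 0.284% and 0.464%). Its shares in T and NK-like cells were 0% (up to 2.63%), 0% (up to 3.33%) and 0.676%.

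The comparison of 3 days with chow asks how Kupffer cells differ early in exposure to the ethanol diet. Ethanol oxidation in the liver alters redox balance and lipid flow, and a leaky gut brings more bacterial products to the sinusoids. Kupffer cells answer such signals with cytokines, scavenger receptors and lipid handling genes. Of the 3516 Kupffer-like cells at 3 days, most were in clusters 4 and 1, and of the 2277 in chow most were in cluster 3.

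The gene with the highest ratio was Ttc39c, which encodes a tetratricopeptide-repeat protein of little-known function (ENSMUSG00000024424, chromosome 18, 12599896 to 12738863). It had 143 CPM at 3 days and 7.38 CPM in chow, a ratio of 19.4 (95% interval 15.5 to 24.5). The ratio lay between 8.10 and 33.3 within the 7 clusters. Ccl9, a chemokine for myeloid cells (ENSMUSG00000019122, chromosome 11, 83572919 to 83578636), had 84.3 against 9.39 CPM, a ratio of 8.98 (7.32 to 11.1). Vcam1, the adhesion receptor for integrin-bearing leukocytes (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), had 992 against 321 CPM. Its ratio was 3.10 (2.98 to 3.22), and 1.83 to 2.89 within clusters. Klf4, a transcription factor of alternative activation that is also an immediate-early gene (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), had 59.2 against 23.9 CPM, a ratio of 2.48. Plin2, which coats lipid droplets (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), had 233 against 104 CPM. Its ratio was 2.25 (2.10 to 2.41), and 1.64 to 5.46 within clusters.

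The other named genes with higher values were of several kinds. Acot1, an acyl-CoA thioesterase driven by fatty acid signalling, had a ratio of 3.11 (2.65 to 3.67), and the immediate-early factor Egr1 one of 2.80. Engase, which trims sugar chains from proteins, had a ratio of 2.62. Sult1a1, a sulfotransferase inducible by glucocorticoids, had 2.58 (2.35 to 2.83), and the actin regulator Inf2 had 2.36.

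Of the genes with the lowest ratios, the immunoglobulin light chain Igkc comes from plasma cells, and its ratio of 0.0666 goes with free RNA. In barcodes with few UMIs it had 758 CPM in chow, 46.2 at 3 days and 73.4 at 10 days. Tfrc, the transferrin receptor for iron uptake, had 27.8 against 73.0 CPM, a ratio of 0.381 (0.333 to 0.434). Ccnd1, the cyclin of entry into the cell cycle, had 70.8 against 157 CPM, a ratio of 0.450 (0.414 to 0.490). Tgm2, a transglutaminase linked to uptake of dying cells, had 179 against 372 CPM, a ratio of 0.481 (0.456 to 0.507). The potassium channel Kcnj10 had a ratio of 0.412, the interferon-induced GTPase Gbp2 0.503, and the tetraspanin Tspan15 0.509. The endoplasmic reticulum cofactor Sdf2l1 had 0.527, the macrophage surface protein Ms4a7 0.581, and the insulin-degrading protease Ide 0.592. Each of the 20 genes had the same direction in all 7 clusters except Ms4a7, with 5 of 7.

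Genes for fatty acid uptake, storage and oxidation were mostly higher at 3 days. The median log2 ratio of the 16 measured members of 23 was 0.27, at percentile 99.8 of random lists. Plin2 and Cd36, with ratios of 2.25 and 1.73, were the 2 members above 1.5, and none was below 1/1.5. LXR targets, which the oxysterol receptor induces for cholesterol export and lipogenesis, had a median of 0.31 over 13 members (percentile 100). Their largest ratios were those of the cholesterol exporter Abca1 (360 against 229 CPM, 1.57) and the lipoprotein lipase Lpl (1.36). Cholesterol synthesis genes, driven by SREBP2, had a median of −0.34 over 7 of 20 members (percentile 0.1). The factor Srebf2 itself had 17.2 against 27.1 CPM (0.634). Within the 7 clusters the LXR median lay between 0.00 and 0.44, the fatty acid median between 0.02 and 0.41 and the cholesterol median between −0.73 and −0.29. With each cluster weighted equally, the LXR median of 0.17 and the fatty acid median of 0.086 were inside the random range, while the cholesterol median was −0.59.

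Antigen presentation genes were lower at 3 days. All 8 measured class II genes of 9 had ratios below 1, with a median log2 ratio of −0.42 (percentile 0.0). The class II master regulator Ciita had 8.80 against 14.8 CPM (0.596), and the class II chain H2-Ab1 a ratio of 0.713 (0.700 to 0.726). The class II median was −0.16 with each cluster given equal weight, inside the random range, and above 0 in 1 of 7 clusters, so the mix of clusters and the level within them were not separated. Class I genes had a median of −0.21 over 12 members (percentile 0.4), with the immunoproteasome subunit Psmb8 at 0.667 and the nonclassical class I gene H2-Q7, in the other direction, at 1.38. Type I interferon response genes had a median of −0.17 over 28 members (percentile 0.0), but the median was above 0 in 4 of 7 clusters. The T cell attractant Cxcl9, which interferon gamma drives more strongly, had 20.2 against 45.8 CPM (0.441).

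Several stress and signalling lists were higher in sums over all Kupffer-like cells. Heat shock, unfolded protein response and NRF2 genes stayed inside the random range. Glucocorticoid targets had a median of 0.61 over 9 of 15 members (percentile 100), with 5 above 1.5, among them the phosphatase Dusp1 (589 against 273 CPM, 2.16) and Sult1a1. Immediate-early genes, which tissue dissociation induces, had a median of 0.62 over 17 of 20 members (percentile 100), with 10 above 1.5. Dusp1 and Klf4 belong to this list as well as to others. Without its immediate-early member, the glucocorticoid list had a median of 0.51 over 8 members. For Klf4 and the anti-inflammatory list, activation during handling was not separated. Anti-inflammatory and alternative activation genes had a median of 0.33 over 10 of 17 members (percentile 99.9), with Klf4 and Cd163 (1216 against 549 CPM, 2.21, 2.15 to 2.28) in front. Apoptosis and p53 genes had 0.23 over 12 of 18 members (98.8), with the cell cycle inhibitor Cdkn1a at 2.43 and Pmaip1, which promotes cell death, at 1.82. Hypoxia genes had 0.26 over 8 of 16 members (97.8). The vasoactive peptide Adm was at 1.45 and the lactate dehydrogenase Ldha at 0.758. With each cluster weighted equally, the anti-inflammatory (0.21), apoptosis (0.050) and hypoxia (0.093) medians were inside the random range, and the immediate-early median was 0.34.

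Inflammatory cytokine and NF-kB genes had a median of 0.12 over 22 of 29 members, inside the random range (percentile 88.1). The chemokines Ccl4 (67.2 against 37.0 CPM, 1.81) and Ccl3 (30.05 against 18.5 CPM, 1.62) were among 4 members above 1.5. Chemokines and growth factors for recruitment had 0.20 over 14 of 20 members (98.8), with Ccl9 and Ccl6 (1892 against 906 CPM, 2.09) highest, and 0.15 with each cluster weighted equally, inside the random range. Toll-like receptor and LPS sensing genes had 0.18 over 20 of 24 members (98.0), none above 1.5. The LPS co-receptor Cd14 was at 1.45 and the adaptor Tirap at 1.44. NRF2 oxidative stress genes stayed inside the random range, with 0.05 over 19 of 23 members. Hmox1, which haem also induces, had a ratio of 1.57 (1.54 to 1.60), and the superoxide dismutase Sod1 had 1.48.

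Energy genes were lower at 3 days. Glycolysis genes had a median of −0.22 over 14 of 17 members (percentile 0.1), with Gapdh at 0.672 and the hexokinase Hk3 at 0.720. Nuclear genes of oxidative phosphorylation had −0.23 over 26 members (0.0), with 23 below 1. The ATP synthase subunit Atp5e was at 0.765, and Uqcrh of complex III, in the other direction, at 1.37. Monocyte genes had −0.21 over 6 of 18 members (2.0, mean −0.01), with the integrin Itgam at 0.531 and the fractalkine receptor Cx3cr1 at 4.51 (3.13 to 6.66). With each cluster weighted equally, the oxidative phosphorylation (−0.074) and monocyte (−0.060) medians were inside the random range. Hepatocyte genes, whose source in these cells was not tested, had 0.28 over 17 of 30 members (99.8). Their apolipoproteins Apoc3 and Apoa2 had ratios of 3.12 and 2.17. Subtraction of free RNA, with a share taken from Kupffer transcripts in T and NK-like cells, reversed these values, to a median of −3.14 and log2 ratios of −3.14 and −5.50, so their direction depends on how free RNA is treated.

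Other lists stayed inside the random range at 3 days. Medians were 0.02 for iron and haem handling (18 of 19 members, mean −0.03), −0.02 for complement (14 of 16), 0.09 for phagocytosis and scavenger receptors (19 of 20) and −0.00 for lysosome and autophagy (26 of 30). They were −0.02 for the unfolded protein response (18 of 21), 0.22 for heat shock (9 of 12), 0.13 for proliferation (17 of 27) and 0.06 for the circadian clock (5 of 17). The lists of lipid-associated macrophages (7 of 13, mean 0.03) and of Kupffer subset 2 (5 of 9) had −0.03 and 0.16. Medians were −0.07 for ribosomal proteins (33 members) and 0.04 for mitochondrially encoded genes (13 members). The markers of sinusoidal endothelium (7 of 20) and conventional dendritic cells (7 of 14) had −0.04 and −0.00, the latter with a mean of 0.04. Subtraction of free RNA by the planned rule turned the cholesterol list to 1.43, and it also turned the class I, glycolysis, oxidative phosphorylation and monocyte lists. Of the 17 lists outside the random range at 3 days, 8 stayed outside that range, which was drawn for sums over all Kupffer-like cells, with each cluster weighted equally. These were the interferon, class I, cholesterol, Toll-like receptor, glycolysis, immediate-early, glucocorticoid (0.56) and hepatocyte lists. The inflammatory list was −0.051 with this weighting. The interferon list had −0.14 with it, but its median was positive in clusters 1, 2, 3 and 4 and lowest in cluster 8 (−0.54), which held 44 cells in chow.

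**Figure D1:**
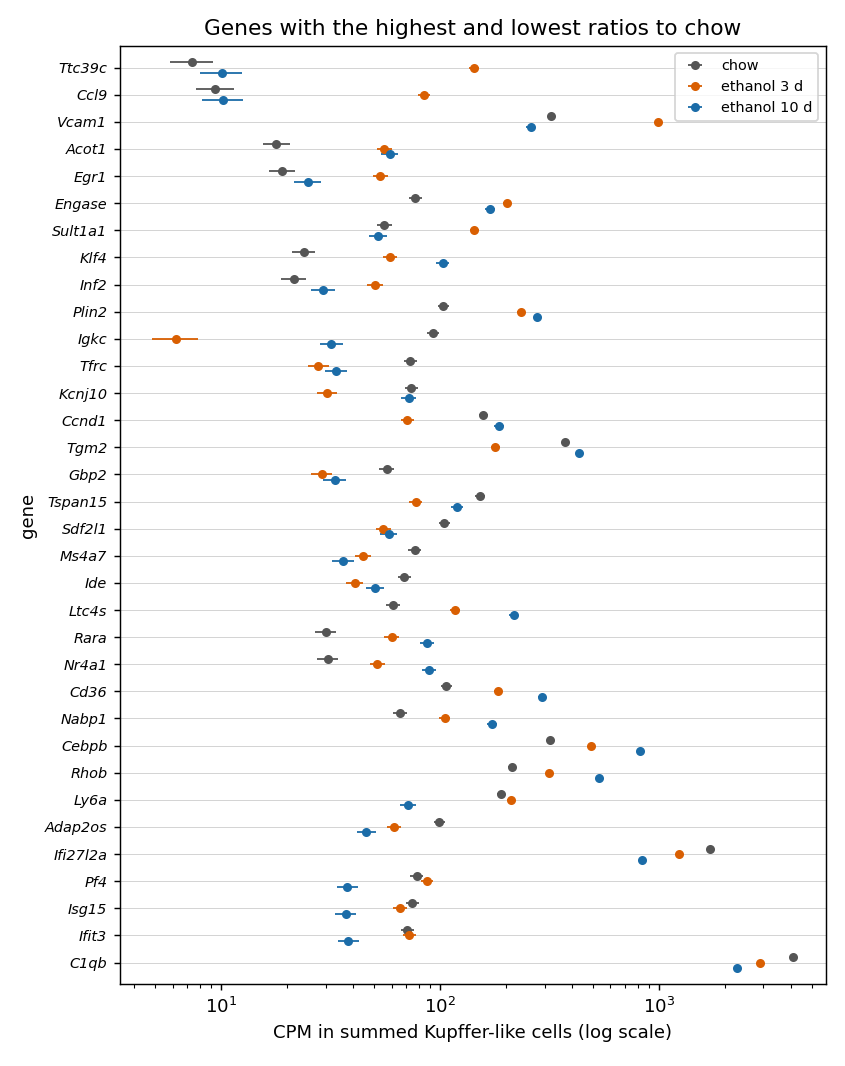
Level of the named genes in Kupffer-like cells, in CPM (UMI counts scaled to library total) on a log axis, with 1 point per library (chow, 3 days and 10 days of ethanol diet) and exact 95% intervals for counting error only. Ttc39c lies at 7.38, 143 and 10.1 CPM and Plin2 at 104, 233 and 278 CPM.

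The comparison of 10 days with chow asks which differences are present after a longer time on the ethanol diet. Fat accumulates in the liver over such feeding, and macrophages that take up lipid oxidise it, store it in droplets or pass it on to lipoproteins. Interferon and antigen presentation programmes set how readily macrophages engage lymphocytes. Most of the 2585 Kupffer-like cells at 10 days were in clusters 2 and 5, and most of those of chow in cluster 3.

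Klf4 had the highest ratio, with 103 CPM at 10 days and 23.9 CPM in chow (4.29, 3.73 to 4.95). Ltc4s, which makes leukotriene C4 (ENSMUSG00000020377, chromosome 11, 50236461 to 50238616), had 217 against 60.9 CPM (3.56, 3.26 to 3.90). Acot1 had 59.1 against 17.9 CPM (3.31, 2.80 to 3.92), and Plin2 had 278 against 104 CPM (2.69, 2.5 to 2.89). Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) had 292 against 107 CPM. Its ratio was 2.74 (2.55 to 2.94), and 1.68 to 2.62 within clusters. The retinoic acid receptor Rara had a ratio of 2.92 and the immediate-early nuclear receptor Nr4a1 2.91. Nabp1, a single-strand DNA binding protein, had 2.63, the small GTPase Rhob 2.49, and Cebpb, a transcription factor of macrophage activation, 2.55 (2.45 to 2.66).

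Genes with the lowest ratios included interferon-induced genes. Ifi27l2a, one of these (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), had 833 CPM against 1708 CPM in chow. Its ratio was 0.488 (0.474 to 0.501), and 0.388 to 0.757 within clusters. The ubiquitin-like modifier Isg15 had 37.0 against 74.7 CPM (0.495, 0.433 to 0.565), and Ifit3, which restrains viral RNA, had 0.538. Ly6a, a surface protein also induced by interferon, had 71.4 against 190 CPM (0.377, 0.343 to 0.413), lower in 5 of 7 clusters. Tfrc had a ratio of 0.459 and Igkc one of 0.343. The platelet factor Pf4 had 0.482, Ms4a7 0.469, the long noncoding RNA Adap2os 0.463, and the complement component C1qb 0.556 (2266 against 4075 CPM). Pf4, Ms4a7 and Adap2os were lower in 5 of 7 clusters, and Rara, Nr4a1, Isg15, C1qb and Igkc had their direction in 6 of 7. The remaining named genes had it in all 7.

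Lipid handling lists lay higher than in chow. The fatty acid list had a median log2 ratio of 0.33 (percentile 99.9), with 6 members above 1.5, and the LXR list had 0.46 (percentile 100), with 5 above 1.5. The desaturase Scd1 had 262 against 109 CPM (2.40, 2.24 to 2.58), and Lpl had 1.72. Both medians were above 0 in all 7 clusters, between 0.13 and 0.35 for fatty acid genes and between 0.08 and 0.58 for LXR targets. With each cluster weighted equally they were 0.17 and 0.23, inside the random range. With genes of at least 50 CPM alone, the fatty acid median was 0.61. The cholesterol list had −0.16, inside the random range (percentile 6.7), with Srebf2 at 0.770. Its median was nevertheless below 0 in all 7 clusters, between −1.36 and −0.23, and was −0.44 with each cluster weighted equally.

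The type I interferon list had a median of −0.50 (percentile 0.0), with 12 of 28 members below 1/1.5 and 1 above 1.5. The median was below 0 in all 7 clusters, between −0.60 and −0.22. Class II genes had −0.52 (0.0), again with all 8 below 1, led by Ciita (0.608) and Cd74 (4906 against 7383 CPM, 0.664). The class II value was −0.14 with each cluster weighted equally, inside the random range. Class I genes had −0.34 (0.0), with the peptide transporter Tap1 at 0.615 and Psmb8 at 0.656.

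The inflammatory list had a median of 0.23 (percentile 98.8), with 3 members above 1.5 and 2 below 1/1.5. It was 0.0068 with each cluster weighted equally. Its members went both ways, with Ccl4 at 2.28 and the monocyte attractant Ccl7 at 0.404. The recruitment list had −0.19 (0.7), with Pf4 and Ccl7 among 3 members below 1/1.5, and −0.072 with each cluster weighted equally. Anti-inflammatory genes had 0.25 (96.4) and Toll-like receptor genes 0.12 (73.5), both inside the random range. In the NRF2 list, with 0.08 (54.5), Hmox1 had a ratio of 1.74 and the biliverdin reductase Blvrb one of 0.685. Iron and haem genes had −0.22 (0.4), with Tfrc at 0.459 and the haem carrier Hpx at 0.271, the latter a hepatocyte product at 4.19 against 15.5 CPM. The iron and haem median was −0.13 with each cluster weighted equally, inside the random range.

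Several stress lists were higher in sums over all Kupffer-like cells. Of these, only heat shock genes stayed outside the random range with each cluster weighted equally (0.36). With that weighting immediate-early genes had 0.095, the unfolded protein response 0.061, apoptosis and p53 genes 0.16 and glucocorticoid targets −0.050. In the sums, immediate-early genes had a median of 0.59 (percentile 100), with Nr4a1 and Dusp1 (2.25) among 9 members above 1.5. Heat shock genes had 0.49 (100), with the chaperones Dnaja1 at 1.69 and Hspa8 at 1.65. Glucocorticoid targets had 0.35 (99.3), with Cebpb and Dusp1 in front. The unfolded protein response had 0.24 (97.7), with Herpud1, which helps degrade misfolded proteins, at 1.91 and Sdf2l1 at 0.557. Apoptosis and p53 genes had 0.26 (97.7), with Cdkn1a at 1.90 and Pmaip1 at 1.82.

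Signs of RNA quality and of other cells differed in the same library. Mitochondrially encoded genes had a median of 0.39 (percentile 100), with mt-Nd4l at 1.43 and mt-Nd3 at 1.42, and mitochondrial UMIs were 6.28% of the total against 5.10% in chow. Ribosomal protein genes had −0.33 (0.0), with Rplp0 at 0.577 and Rps2 at 0.603. Nuclear oxidative phosphorylation genes had −0.25 (0.0), 24 of 26 below 1, with Sdhb at 0.667 and Atp5g1 at 0.669. Glycolysis genes had −0.19 (0.1), with Gapdh at 0.725 and the regulator Pfkfb3 at 0.726. Hepatocyte genes had −0.41 (0.0), with the protease inhibitor Serpina3k at 0.476 and albumin (Alb) at 0.512. With each cluster weighted equally, mitochondrially encoded (0.18), ribosomal protein (−0.079) and oxidative phosphorylation genes (−0.035) were inside the random range, and hepatocyte genes had −0.11. Over all kept cells, rather than Kupffer-like cells, the hepatocyte median was 0.42 and the Alb log2 ratio 0.25. With the free RNA share from T and NK-like cells subtracted, the median was −1.29.

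The other lists stayed inside the random range at 10 days. Medians were 0.28 for hypoxia, −0.02 for complement, 0.06 for phagocytosis, 0.08 for lysosome and autophagy, 0.19 for proliferation and 0.17 for the circadian clock. They were −0.18 for monocyte genes (mean 0.03), 0.05 for lipid-associated macrophages, 0.12 for Kupffer subset 2, 0.04 for sinusoidal endothelium and 0.20 for conventional dendritic cells. Erythroid genes, of which 4 of 12 were measured, had 0.28 at 3 days and 0.13 at 10 days over chow, and −0.16 at 10 days over 3 days. Of the 18 lists outside the random range at 10 days, 5 stayed outside it with each cluster weighted equally, namely interferon (−0.43), class I (−0.23), glycolysis (−0.10), heat shock and hepatocyte genes. The planned subtraction of free RNA turned the cholesterol list to 0.30, and it also turned the class I, recruitment, iron, glycolysis and oxidative phosphorylation lists.

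**Figure D2:**
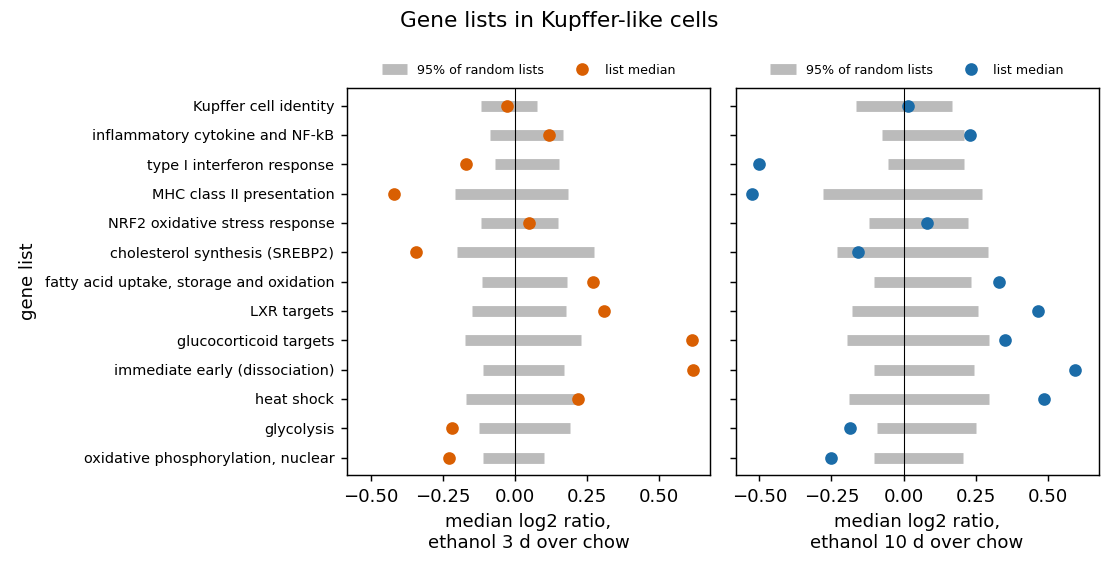
Median log2 ratio over chow of 13 gene lists in Kupffer-like cells, at 3 days and 10 days of ethanol diet, with grey bars for the range of 95% of the random lists. LXR targets lie at 0.31 and 0.46 and type I interferon genes at −0.17 and −0.50.

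The comparison of 10 days with 3 days asks whether early differences from chow were also present later. Kupffer cells can adapt to repeated stimulation, and an early chemokine or adhesion response need not last. This pair of libraries had similar depth per cell and the same diet form. Most cells at 3 days were in clusters 4 and 1, and most at 10 days in clusters 2 and 5.

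The named genes with lower values at 10 days were Ly6a and 4 genes higher at 3 days than in chow. Ttc39c had 10.1 against 143 CPM, a ratio of 0.0704, and Ccl9 10.2 against 84.3 CPM, a ratio of 0.121. Vcam1 had 259 against 992 CPM (0.261, 0.249 to 0.273), Ly6a had 0.340 and Sult1a1 0.364. At 10 days the ratio over chow was 1.36 (0.992 to 1.87) for Ttc39c, an interval that includes 1, and 0.808 (0.765 to 0.852) for Vcam1. The genes with the highest ratios were Ccnd1 (2.62, 2.41 to 2.86), Tgm2 (2.40, 2.27 to 2.54) and Kcnj10 (2.36), each lower at 3 days than in chow. They were joined by the prostacyclin synthase Ptgis (97.0 against 45.8 CPM, 2.12) and Fam167a, of unknown function (99.2 against 49.3 CPM, 2.01). All 10 genes had these directions in each of the 7 clusters.

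Fatty acid genes were higher at 10 days than at 3 days, with a median of 0.25 (percentile 99.9). The coactivator Ppargc1b, which drives oxidation, had 27.7 against 14.6 CPM (1.89), and Cd36 had 1.59. Cholesterol genes had 0.27 (98.5), with 6 of 7 above 1 and the regulator Insig1 at 1.39. With each cluster weighted equally, the fatty acid (0.074) and cholesterol (0.12) medians were inside the random range. LXR targets had 0.13 (90.4), inside the random range. Interferon genes had −0.39 (0.0), with 5 of 28 below 1/1.5, the deconjugating protease Usp18 at 0.506 and Cxcl9, in the other direction, at 1.99. The recruitment list had −0.23 (0.1), with 6 of 14 below 1/1.5, and was 0.010 with genes of at least 50 CPM alone.

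The inflammatory list had 0.02 (53.7, mean −0.00), with the monocyte attractants Ccl7 at 0.444 and Ccl2 at 0.587. Class II genes had −0.09 (19.9), with H2-DMb1, which loads peptide, at 1.16 and the protease Ctss at 0.885. NRF2 genes had 0.00 (38.4), with Blvrb at 0.798 and the glutathione transferase Mgst1 at 0.785, whose log2 ratio of −0.35 reversed to 0.085 with the free RNA share from T and NK-like cells subtracted. Among identity genes Cd163 was at 0.491 and Marco at 1.69. Class I genes had −0.10 (4.6) and anti-inflammatory genes −0.04 (25.7). Immediate-early genes had −0.00 (31.9, mean 0.08) and glucocorticoid targets 0.11 (80.9, mean −0.12).

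Heat shock genes had 0.29 (99.5) and the unfolded protein response 0.24 (99.9). Mitochondrially encoded genes had 0.34 (100) and ribosomal protein genes −0.30 (0.0). Hepatocyte genes had −0.79 (0.0), with 12 of 17 below 1/1.5, but 0.27 over all kept cells and 1.14 with the free RNA share from T and NK-like cells subtracted. Medians were −0.17 (0.4) for iron and haem genes and 0.31 (99) for sinusoidal endothelial genes. The remaining medians were inside the random range. They were 0.02 for glycolysis, −0.07 for oxidative phosphorylation, 0.12 for hypoxia, 0.02 for apoptosis and p53 (mean −0.02), 0.03 for Toll-like receptors (mean −0.06) and 0.00 for phagocytosis (mean −0.04). They were also −0.01 for complement, 0.09 for lysosome and autophagy, 0.11 for proliferation, −0.05 for the circadian clock (mean 0.15), −0.01 for monocyte genes (mean 0.04), −0.12 for lipid-associated macrophages, 0.06 for Kupffer subset 2 and 0.24 for conventional dendritic cells. Of the 11 lists outside the random range, 6 stayed outside it with each cluster weighted equally. These were interferon (−0.22), the unfolded protein response (0.22), ribosomal protein (−0.15), mitochondrially encoded (0.37), hepatocyte (−0.67) and sinusoidal endothelial genes (0.38). Cholesterol (0.12), fatty acid (0.074), iron (−0.093), heat shock (0.21) and recruitment genes (−0.067) moved inside it. The planned subtraction of free RNA turned the cholesterol value to −0.40, the inflammatory value to −0.19 and the class II value to 0.28.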

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

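Among the tests below, those of free RNA and of damaged cells were chosen after the result they bear on had been seen. For 6 named genes the difference from chow had opposite directions at 3 days and at 10 days, with a 95% interval that excluded 1 at both times. The log2 ratio of 10 days over 3 days was −1.93 for Vcam1, −1.54 for Ly6a and −1.19 for Pf4. It was 1.38 for Ccnd1, 1.26 for Tgm2 and 0.99 for Fam167a. Vcam1 had log2 ratios over chow of 1.63 at 3 days and −0.31 at 10 days, Ly6a of 0.15 and −1.40, and Pf4 of 0.16 and −1.03. Ccnd1 had −1.14 and 0.24, Tgm2 −1.05 and 0.21, and Fam167a −0.32 and 0.68. With 1 mouse per time, these differences between the times were not tested.

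A further signal lies in barcodes with few UMIs, which hold free RNA rather than cells. Gm42418, a noncoding locus that overlaps ribosomal RNA sequence, had 5397 CPM there in chow, 4810 at 3 days and 21729 at 10 days. The ratio of 10 days over chow was 4.03 (3.97 to 4.09) over 64449 and 65042 barcodes. In Kupffer-like cells the gene had 1659, 1868 and 3611 CPM. The source of this RNA was not tested.

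The first pattern weighed is that Kupffer-like cells of the 3 libraries lay mostly in different clusters. On average 69.7% of a cell's 15 nearest neighbours came from its own library, against 33.3% expected with random mixing, an excess of 36.4 points. Depth is argued against as the whole cause, since the excess was 23.4 points with cells thinned to 1500 UMIs. Thinning removes the difference in depth and also adds sampling noise, and these were not separated. The excess was 35.3 points after 158 immediate-early, heat shock, mitochondrially encoded and ribosomal protein genes were left out. With thinning as well it was 22.0 points. This argues against these genes as the whole cause. Other genes that handling can change stayed in, so handling itself stays open. For the named genes, the difference in T and NK-like cells had a median of 5.32% of that in Kupffer-like cells. The median is over 50 gene comparisons, in which some genes recur. In 1 of them the difference was at least as large in T and NK-like cells. Free RNA is argued against as the source of most of these differences, while genes outside this set were not covered. The diet, its liquid form, the mouse and the preparation stay open and untested, since each library is 1 group.

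The second pattern is that 18 genes, among them Ttc39c, Ccl9, Vcam1, Sult1a1, Cd163 and Ccl6, were higher at 3 days than in both other libraries by over 1.5 times, with both 95% intervals excluding 1 and at least 50 CPM at 3 days. By the same fold and intervals 8 were lower, with at least 50 CPM in chow or at 10 days. Genes left out of the ranking of named genes were left out here too. The 18 genes also held the immediate-early genes Egr1 (ratio over chow 2.80) and Fos (1.97), and handling was not tested for this pattern. Cells of 1 cluster are argued against as the source, because the median ratio over chow was 1.92 outside cluster 4, against 1.86 in all Kupffer-like cells and 1.63 within that cluster. Free RNA is argued against by a median difference in T and NK-like cells of 6.23% of that in Kupffer-like cells. A response to the ethanol diet that differs with time may explain the pattern, and so may a feature of that 1 mouse or preparation, which was not tested.

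The third pattern is that the type I interferon list was lower at 10 days than in both other libraries. Damaged cells are argued against, since the log2 median over chow was −0.59 among cells with at most 5% mitochondrial UMIs (992 and 365 cells). A few strongly responding cells are argued against by a median of −0.51 without the 10% of cells highest in the list. A lower interferon response throughout the sorted cells is consistent with a median of −0.44 over 9 members in T and NK-like cells and −0.45 in endothelial-like cells, although T and NK-like cells also hold free RNA of Kupffer cells. At 10 days over 3 days the median was −0.81 in T and NK-like cells and −0.09 in endothelial-like cells, inside a wide random range of −0.27 to 0.26. Single members went both ways there, with Isg15 at a ratio of 0.283 (0.0957 to 0.696), Rtp4 at 0.298 (0.154 to 0.538) and Igtp at 3.39 (1.35 to 9.61), so that part of the pattern stays open for these cells. Whether the diet or the mouse lowered it was not tested.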

How the results depend on the processing

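The tests with free RNA taken from T and NK-like cells, without clusters 1, 2 or 8 and with each cluster weighted equally were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Of the values under alternatives, 26 of 30 class shares, 473 of 501 medians of the 7 main lists, 1823 of 1941 medians of other lists and 2432 of 2898 ratios of named genes stayed within their counting interval or, for medians, within the spread of random lists. That spread was set as the limit once the data were at hand. Reversals numbered 0 for shares, 2 for main lists, 22 for other lists and 37 for genes, and medians and ratios are log2 values here. The 2 filters on low values applied to lists alone and the pseudocount to genes alone, and settings that act after clustering gave no shares.

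The planned subtraction of free RNA gave most of these. It removed 87.7%, 45.4% and 75.9% of the UMIs in chow, at 3 days and at 10 days, because it forces 41 hepatocyte and erythroid genes to 0. Kupffer transcripts in T and NK-like cells point to 8.12%, 7.89% and 8.75%, so the planned share is too large by its own construction. Under it the log2 ratio over chow at 10 days was 0.00 for Alb, Hpx, Igkc, Ly6a, Nr4a1, Serpina3k and Tfrc. At 3 days it was 0.00 for Apoa2, Apoc3 and Igkc, and Mgst1 had 0.00 at 10 days over 3 days. At 3 days over chow it was 1.75 for Atp5e, 2.51 for H2-Ab1, 0.45 for Hk3, 3.77 for Itgam, 6.62 for Ldha, −0.35 for Lpl, 7.50 for Psmb8, 3.89 for Srebf2, 4.27 for Tfrc and −0.31 for Tirap. At 10 days over chow it was 2.21 for Ccl7, 0.26 for Ifit3, 0.93 for Pf4, 6.65 for Psmb8, 0.40 for Sdhb, 3.49 for Srebf2, 4.87 for Tap1, −8.20 for mt-Nd3 and −8.60 for mt-Nd4l. At 10 days over 3 days it was 0.047 for Blvrb, 0.20 for Ctss and −5.09 for Ptgis.

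List medians under the same subtraction, at 3 days over chow, were −0.20 for Kupffer identity, 4.19 for MHC class I presentation, 0.25 for NRF2, 1.43 for cholesterol synthesis, 0.25 for glycolysis, 0.00 for hepatocyte genes, 2.15 for inflammatory genes, 3.91 for monocyte genes and 0.30 for oxidative phosphorylation. At 10 days over chow they were 0.23 for Kupffer identity, 2.04 for class I, −0.14 for class II, 0.38 for NRF2, 0.82 for chemokines, 0.30 for cholesterol, 0.47 for glycolysis, 0.00 for hepatocyte and mitochondrially encoded genes, 2.23 for inflammatory genes, 0.079 for iron and haem and 0.22 for oxidative phosphorylation. At 10 days over 3 days they were 0.22 for Kupffer identity, 0.28 for class II, −0.40 for cholesterol, 0.45 for fatty acids, 0.00 for hepatocyte and sinusoidal endothelial genes, −0.19 for inflammatory genes, 0.026 for iron and haem, −7.75 for mitochondrially encoded genes and −0.23 for interferon genes.

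With the free RNA share from T and NK-like cells, Apoa2 and Apoc3 had −5.50 and −3.14 at 3 days over chow, and Mgst1 had 0.085 at 10 days over 3 days. The hepatocyte list had −3.14 and 1.14 in those comparisons. With each Kupffer-like cluster weighted equally, medians over chow at 3 and 10 days were −0.16 and −0.14 for class II, −0.59 and −0.44 for cholesterol, and −0.051 and 0.0068 for inflammatory genes. Fatty acid genes had 0.086 at 3 days over chow and 0.074 at 10 days over 3 days, glucocorticoid targets −0.050 at 10 days over chow, and interferon genes −0.22 at 10 days over 3 days. Over all cells that passed the filters, Alb had 0.25 and the hepatocyte list 0.42 at 10 days over chow, and that list 0.27 over 3 days, since hepatocyte-like cells were then included. With list members of at least 50 CPM, chemokines had 0.010 at 10 days over 3 days, and fatty acid genes 0.44 at 3 days and 0.61 at 10 days over chow. With at most 5% mitochondrial UMIs the Kupffer-like shares were 80.3%, 85.5% and 61.0%, inflammatory genes had −0.11 at 10 days over 3 days, and interferon genes −0.71 at 10 days over chow. With the 3000 largest barcodes the share at 3 days was 88.3%. Except where the construction of an alternative is named above, the cause was not tested. Leaving out cluster 1, 2 or 8 moved none of the 7 main lists. Clusters 3, 4 and 5, which also follow the libraries, were not left out for the lists, and equal weight per cluster moved 9 values of the main lists. Depth limits genes at low levels, such as Cx3cr1 at 3.28 CPM in chow, whose ratio of 4.51 at 3 days had an interval of 3.13 to 6.66.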

Other observations

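The tests in this part were written before their results were seen, except that the values given for single members, for numbers of cells and for equal weight per cell or cluster were added afterwards. T and NK-like cells passed the sort beside the macrophages, with 115 cells in chow, 90 at 3 days and 153 at 10 days. These lymphocytes patrol the sinusoids and supply interferon gamma and cytotoxic granules. Their T cell list had a median log2 ratio of −0.38 at both times over chow, while their NK list had 0.40 at 3 days. T cells and NK cells were not counted separately, so their mix and their expression were not separated. Proliferation genes had 0.89 at 3 days and −0.86 at 10 days over 3 days. The tubulin regulator Stmn1 had 407 CPM at 3 days and 54.7 CPM in chow, but its UMIs came from 11 and 8 cells. Ifng, the interferon gamma gene, had 93.5, 396 and 29.4 CPM, seen in 27, 15 and 12 cells, so a higher level at 3 days rested on fewer cells. The granzyme Gzma had 208, 546 and 835 CPM in 6, 5 and 13 cells, and the 26 UMIs of the chemokine Ccl1 at 3 days came from 1 cell. Heat shock genes had 0.56 at 3 days, and glycolysis genes −0.41 and −0.53. Class II genes had −0.98 and −0.85 in this class, a value that free RNA of antigen-presenting cells can carry.

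Endothelial-like cells, which line the sinusoids and remove waste molecules, numbered 38, 106 and 71. Their own sinusoidal endothelial markers had median log2 ratios of −0.29 at 3 days and −0.27 at 10 days over chow, both below the range of random lists, and Kupffer identity genes had 0.21 at 3 days, above it. A difference in the makeup or purity of this class was therefore not separated from the values below. Their LXR targets had a median of 0.71 at 3 days and 0.88 at 10 days. Proliferation genes had −0.90 and −1.62, and glycolysis genes −0.97 at 3 days. Stellate and fibroblast genes had 2.21 and 1.94, and at 10 days monocyte genes had 3.82 and class II genes 1.10. At 10 days 2 of the 71 cells held 77.0% of the 483 UMIs of monocyte genes and 65.1% of the 1157 UMIs of class II genes. At 3 days 2 cells held 63.7% of the 369 UMIs of stellate and fibroblast genes, and at 10 days 60.6% of 216 UMIs. In chow 2 of the 38 cells held 38.8% of the 466 UMIs of proliferation genes. LXR target UMIs were seen in every cell of the class, with 19.1%, 22.4% and 15.3% of them in 2 cells. Among single genes, the 283 UMIs of the secreted protein gene Retnla at 10 days came from 1 cell and the 122 UMIs of Spp1 at 3 days came from 2 cells. The 120 UMIs of the protease inhibitor Slpi came from 2 cells at 10 days. In chow the 14 UMIs of the division gene Birc5 came from 3 cells.

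One hypothesis is that sorted cells at 3 days had been exposed to more glucocorticoid. Stress hormones induce Sult1a1, Tsc22d3 and metallothionein genes in many cell types. In endothelial-like cells the glucocorticoid list had a median log2 ratio of 0.78 at 3 days over chow (10 members), above the range of random lists, which is consistent with the hypothesis. The value was 0.62 with each cell weighted equally and 0.45 without the metallothioneins, whose Mt1 and Mt2 had ratios of 2.70 and 3.38, and which zinc and inflammation also induce. In this class Sult1a1 had a ratio of 2.47 (1.08 to 6.58), while Tsc22d3 had 1.75 (0.954 to 3.42) and Dusp1 1.06 (0.748 to 1.52), both with intervals that include 1. In T and NK-like cells Tsc22d3 had 0.587 (0.240 to 1.31), which rests on 9 UMIs at 3 days and 24 in chow and also includes 1. Fatty acid, hepatocyte and immediate-early lists were also higher in endothelial-like cells, at 0.60, 0.46 and 0.35, and endothelial markers were lower, at −0.29. The list may therefore follow handling, the mix of cells in this class or a wider difference between them, and the hypothesis stays open.

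A different hypothesis is that the higher LXR targets at 10 days came from a shift in the mix of Kupffer-like clusters. The list's median lay above 0 in 7 of 7 clusters, which was the bound set beforehand against a shift in the mix. That bound was too weak, because a value above 0 can lie inside the range of random lists. Only 3 of the 7 clusters were above that range, a condition added after the values were seen. The median was 0.23 with each cluster weighted equally, against 0.46 over all Kupffer-like cells. The clusters follow the libraries, so mix and level cannot be told apart, and the hypothesis stays open. Lipid uptake under the diet might raise oxysterols and so these genes, a biological explanation that stays untested with 1 mouse per group.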
